A study of Mus musculus with 12 samples.

How the data were processed

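RNA was measured in 12 cultures of mouse bone-marrow-derived macrophages, 3 for each of 4 genotypes: wild type (WT), Cbl-/-, Cbl-b-/- and the double knockout (DKO). Per the labels' protocols, marrow cells were grown to day 9 with conditioned medium from L cells as the source of the growth factor CSF-1, and the adherent cells were taken for RNA. Stranded libraries of messenger RNA were made with a TruSeq kit, per the labels' protocols. The labels say that RNA was pooled at equal concentrations without saying whether animals or libraries were pooled, and nothing says that replicates came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical.

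The authors deposited a table of read counts per gene, whole numbers with no normalization. Per the submitters' processing notes the genome build was GRCm38.p5, while the aligner, the counting program and its use of strand are not given in the sources used here. The table had 15555 genes, of which 15506 carried a symbol and 49 did not. Each gene had at least 1 count in the library WT 1, while counts of 0 occurred in the other libraries. A gene with no reads in WT 1 therefore had no values, and genes switched on from nothing in another genotype were not analysed here. Total counts ranged from 21048103 to 43946503 per library. Genes with near-identical copies are uncertain, because the treatment of reads that map to more than 1 place is not given in the sources used here. Gene positions came from the GENCODE annotation of GRCm38.

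All 12 libraries were fitted together with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 12671 genes tested and took out 2884. Libraries were scaled with TMM factors, and a model with 1 mean per genotype was fitted by robust quasi-likelihood. Every adjusted p for a gene comes from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the 12671 genes, with a threshold of 0.05 and no minimum fold. Log2 fold changes are given with standard errors (SE), and levels as CPM (counts scaled to library size) computed from the deposited counts with the TMM factors. The 6 pairs of genotypes were compared, with Cbl-b-/- and DKO standing for the libraries so labelled, and a contrast of DKO minus Cbl-/- minus Cbl-b-/- plus WT tested whether the libraries labelled DKO departed from the sum of the effects in both single-knockout labels on the log2 scale.

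The lists, tests, alternatives and naming rule were fixed before the data were examined. There were 31 gene lists with 510 genes in all, 19 for pathways or functions, 10 for other cell types and 2 for a check of sex, and 67 of the genes were absent from the table. The 25 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM values from voom, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of 1 comparison. Each list was tested again with a correlation estimated from the data. Members were also adjusted over the list alone. The genes named are Cbl and Cblb, and, for each comparison with WT, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 1 log2 CPM, a symbol that is not a clone or model name, and all 3 libraries on the same side of all 3 WT libraries. Up to 4 members of each list with the smallest adjusted p were added, or, where a list passed and no member did, the 2 with the smallest p. For the other comparisons the 5 largest in each direction were named. Any other gene was chosen after its values were seen, and this is said where it is named. Results for some genes that the rule names are not reported here.

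The pipeline was tested on simulated counts for the same 12671 genes and library sizes. Of 100 genes changed 1.5-fold and 100 changed 2-fold, it recovered 63% and 76% in simulated Cbl-/- against WT, 68% and 87% in simulated Cbl-b-/- against WT, and 72% and 82% in simulated DKO against WT. False calls made up 4.79%, 7.74% and 2.53% of the genes called in these simulated comparisons. Apart from the changed genes, all simulated libraries shared the same mean and the same spread per gene. The real spread was unequal, with a coefficient of variation of 4.25% in Cbl-/- and 11.9% in DKO. These rates therefore need not hold for the real comparisons.

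Replicates were compared by a chi-square test of their counts over genes with a summed count of at least 20. The statistic per degree of freedom was 3.93 to 55.3 over the 12 pairs of libraries of 1 genotype, so no pair differed as little as sampling noise alone. The alternatives tried were DESeq2 size factors or total counts for scaling, no filter or a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0 and limma voom as tests, the replicate number as a block, a fit of the compared genotypes alone, and leaving out each library in turn. The comparisons with WT share the WT libraries, so their overlaps were set beside 20 simulations of unchanged groups. Simulations against the real WT counts, as planned, held no spread of WT, so a simulation that draws the WT libraries as well was added after the data were seen and is the one given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.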

Results

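The data are read counts per gene from 12 libraries of bone-marrow-derived macrophages, with 3 libraries for each of the genotypes WT, Cbl-/-, Cbl-b-/- and DKO. Cbl and Cbl-b are related ubiquitin ligases that act on activated tyrosine kinases, among them the CSF-1 receptor that drives the growth of these cells. The design asks how the macrophage transcriptome differs when either ligase, or both, is missing. Total counts per library were 27822954 to 42007454 in WT, 23892790 to 35129318 in Cbl-/-, 21048103 to 34099547 in Cbl-b-/- and 32863268 to 43946503 in DKO. The first principal component held 39.6% of the variance and set the 3 DKO libraries (41.4 to 46.8) apart from the other 9, none of which lay above -5.39. The second held 17.4% and set Cbl-/- (-32.1 to -27.0) apart. The third held 11.6%, and on it the library Cbl-b-/- 3, the least deep of all, lay at -39.4 while its 2 partners lay at 7.30 and 10.2. The biological coefficient of variation was 5.41% in WT, 4.25% in Cbl-/-, 7.88% in Cbl-b-/- and 11.9% in DKO.

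The targeted genes were examined first. Cbl (ENSMUSG00000034342, chromosome 9, 44142976 to 44234049, GRCm38) had 140 ± 3.4 CPM in WT (SD, n = 3), 51.5 ± 2.3 in Cbl-/-, 139 ± 3.0 in Cbl-b-/- and 37.6 ± 3.1 in DKO. Its log2 fold change against WT was -1.44 (SE 0.06, adjusted p = 7.4e-11) in Cbl-/- and -1.90 (SE 0.06, adjusted p = 2.4e-12) in DKO, and -0.01 (SE 0.06, adjusted p = 0.99) in Cbl-b-/-. Cblb (ENSMUSG00000022637, chromosome 16, 52031225 to 52208048) had 59.4 ± 3.5 CPM in WT, 68.5 ± 0.69 in Cbl-/-, 52.8 ± 2.9 in Cbl-b-/- and 71.7 ± 3.2 in DKO (SD, n = 3). Its log2 fold change was -0.17 (SE 0.06, adjusted p = 0.46) in Cbl-b-/-, so no loss of the transcript was detected there, and 0.27 (SE 0.06, adjusted p = 0.0027) in DKO, where it rose. In Cbl-/- it was 0.20 (SE 0.06, adjusted p = 0.048), which passed the threshold but lost it without the filter on low counts (adjusted p = 0.059) and with the replicate number as a block (adjusted p = 0.060). The call was also lost without WT 1, WT 2, WT 3, Cbl-/- 1, Cbl-/- 2 or Cbl-/- 3 (log2 fold changes 0.24, 0.16, 0.22, 0.21, 0.21 and 0.20). Counts summed over a whole gene cannot show a disruption that leaves the transcript in place. The Cblb counts thus do not bear out the labels Cbl-b-/- and DKO, and these groups are called the libraries labelled Cbl-b-/- and labelled DKO from here on, with every direction drawn from them resting on the labels.

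**Figure D1:**
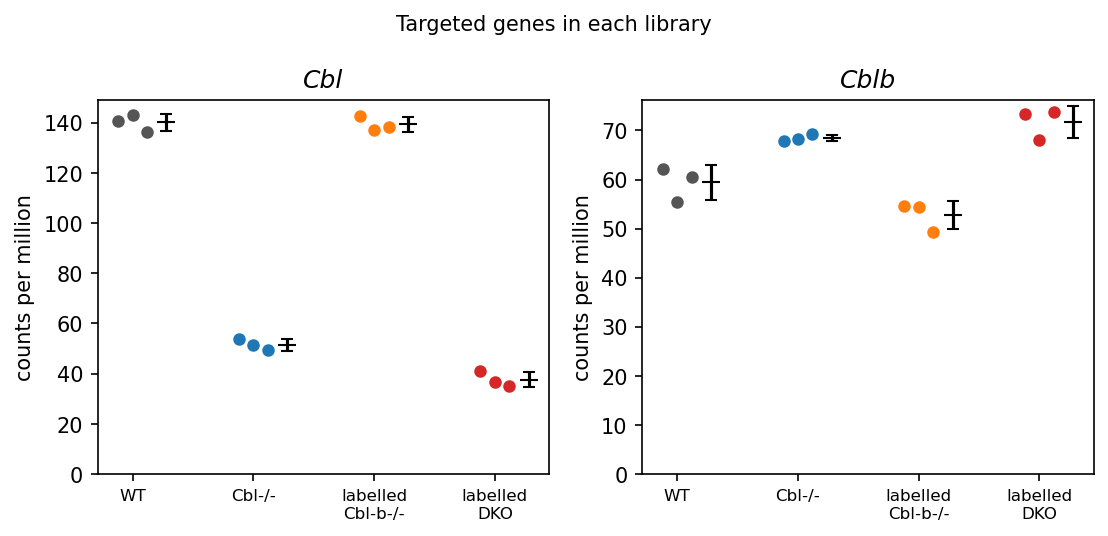
CPM (vertical axes, from 0) of Cbl and Cblb in each of the 12 libraries, grouped by genotype; points are libraries and the black marks are the mean and 1 SD of 3. Cbl lies at 51.5 in Cbl-/- and 37.6 in the libraries labelled DKO against 140 in WT, while Cblb lies between 52.8 and 71.7 in all 4 group means.

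In Cbl-/- macrophages, 20 of 22 genes of mitosis and 15 of 25 of inflammatory signalling were higher than in WT. Uchl1, a deubiquitinating enzyme best known from neurons, rose the most of the genes that met the naming rule, from 14.1 ± 1.7 to 201 ± 5.6 CPM (SD, n = 3). The receptors for complement fragment C5a were both higher, C5ar2 from 2.74 ± 0.17 to 24.7 ± 1.5 CPM and C5ar1 from 252 ± 45 to 786 ± 100.3. Acod1, which makes the antimicrobial metabolite itaconate, rose 6.54-fold, and Cd40, a costimulatory receptor, rose 6.11-fold. The interferon-induced gene Ifi44l fell from 10.8 ± 2.1 to 0.0768 ± 0.083 CPM and its neighbour Ifi44 from 38.4 ± 6.6 to 3.58 ± 1.0.

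Of the 12671 genes tested, 1251 differed between Cbl-/- and WT, 720 higher and 531 lower, with 124 higher and 83 lower by at least 2-fold. Uchl1 (ENSMUSG00000029223, chromosome 5, 66676091 to 66687234) had a log2 fold change of 3.84 (SE 0.08, adjusted p = 8.5e-15). The next largest increases within that rule, which leaves out genes of low mean level, were Fkbp9 (3.38), C5ar2 (ENSMUSG00000074361, chromosome 7, 16234585 to 16244154; 3.18, SE 0.12), Nectin1 (3.16), Neo1 (3.07), the paired immunoglobulin-like receptor gene Pira2 (2.74), Acod1 (2.71), the RNA-binding protein gene Igf2bp3 (2.70), Cd40 (2.61) and Fam162a (2.40). Among the decreases, Ifi44l (ENSMUSG00000039146, chromosome 3, 151758737 to 151762892) had -7.26 (SE 0.32, adjusted p = 1.0e-10) and Hmga1b (ENSMUSG00000078249, chromosome 11, 120762794 to 120764419) -6.83 (SE 0.27). Hmga1b is a near-identical copy of Hmga1, which was chosen after its values were seen and rose by 1.33, so reads could have been split between them. Lower too were Stard13 (-5.74), the ceramide synthase gene Cers4 (-3.93), Ifi44 (-3.39), Plbd1 (-2.62), the lipid flippase gene Atp10d (-2.54), Bcl2a1d (-2.30), Cnbd2 (-2.28) and Sbk2 (-2.09). Each of these genes had all 3 Cbl-/- libraries on 1 side of all 3 WT libraries, as the rule for naming them required. Pira2 and Bcl2a1d belong to families of close copies and are uncertain for the same reason as Hmga1b. Nectin1, at 43743984 to 43807461 on chromosome 9, lies within 1 Mb of Cbl.

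The mitosis list rose nearly as a whole: 20 of 22 genes rose, 0 fell and 2 did not pass, and 22 rose when adjusted over the list alone (camera adjusted p = 6.8e-20, and adjusted p = 0.041 with an estimated correlation). The changes were small, with a median of 0.33. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 0.47 (SE 0.06), the kinase gene Aurka by 0.39 (SE 0.05), cyclin Ccnb2 by 0.41 (SE 0.06) and the proliferation marker Mki67 by 0.41 (SE 0.07). In the DNA replication list 2 of 24 genes rose, Rrm2 and Uhrf1, 1 fell, the thymidylate synthase gene Tyms (-0.32), and 21 did not pass (5 rose and 1 fell adjusted over the list alone; adjusted p = 3.5e-04, and adjusted p = 0.047 with an estimated correlation). Of 25 inflammatory cytokine and NF-kB target genes, 15 rose, 0 fell and 10 did not pass, with 18 and 1 adjusted over the list alone (adjusted p = 4.5e-18, and adjusted p = 0.013 with an estimated correlation). They included the signalling inhibitor Socs3 (1.74, SE 0.11), the neutrophil chemokine Cxcl2 (1.57, SE 0.12), the adhesion molecule Icam1 (0.77, SE 0.06) and Cd40. In the libraries labelled DKO, where Cbl was lower as well, the mitosis list did not pass against WT. There 7 of 22 mitosis genes rose, 0 fell and 15 did not pass by either adjustment, with a median of 0.07. The list had a camera adjusted p = 0.13 there, and adjusted p = 0.58 with an estimated correlation.

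The other 5 lists that passed camera in Cbl-/- did so only with the preset correlation. Of 13 genes of MHC class II presentation, 5 fell, 1 rose and 7 did not pass (6 and 1 adjusted over the list alone; adjusted p = 0.0011, adjusted p = 0.16 with an estimated correlation), with H2-Eb1 at -1.05, H2-Aa at -0.84 and Cd74, the invariant chain, at -0.62. Of 17 chemokine receptor and migration genes, 8 rose, 2 fell and 7 did not pass (9 and 3 adjusted over the list alone; adjusted p = 0.0038, adjusted p = 0.10 with an estimated correlation), among them C5ar1 up by 1.64 and the chemokine receptors Cxcr4 and Cx3cr1 at -0.74 and -0.47. In the list of tyrosine kinase signalling partners of Cbl, 9 of 30 rose, 0 fell and 21 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.0029, adjusted p = 0.16 with an estimated correlation). The risers were led by the receptor gene Met (1.38) and the Src-family kinase genes Fgr (0.91) and Src (1.55), whereas Csf1r, the CSF-1 receptor gene, chosen after its values were seen, was at -0.01 (adjusted p = 0.96). In the list of LXR targets and lipid efflux 7 of 18 rose, 2 fell and 9 did not pass (7 and 3 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.35 with an estimated correlation), with the scavenger receptor Cd36 up by 0.94 and the cholesterol exporter Abca1 up by 0.88. Of 26 interferon response genes, 5 rose, 1 fell and 20 did not pass, with the same counts adjusted over the list alone (adjusted p = 2.1e-04, adjusted p = 0.45 with an estimated correlation). Cxcl10 (1.43) and the guanylate-binding protein gene Gbp2 (0.79) rose while Ifi44 fell. Without the library WT 1 the number of genes called fell to 733, and without WT 2 or Cbl-/- 1, 2 or 3 it was 801, 799, 803 or 784. With only Cbl-/- and WT in the fit it was 2753.

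The libraries labelled Cbl-b-/- differed from WT in few genes, and most of those were higher. C5ar2 rose the most of the genes that met the naming rule, from 2.74 ± 0.17 to 16.3 ± 1.6 CPM (SD, n = 3), and C5ar1 rose from 252 ± 45 to 517 ± 18. Acod1 rose 2.76-fold and the chemokine gene Cxcl2 2.36-fold. The small decreases included Ifi44, Ifi44l and Ly86, which encodes a partner of the receptor RP105.

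In this comparison 62 genes passed, 50 higher and 12 lower, of which 12 and 1 changed at least 2-fold. C5ar2 had a log2 fold change of 2.57 (SE 0.12, adjusted p = 4.4e-09). Within the naming rule it was followed by Pira2 (1.71), Acod1 (1.47), Cxcl2 (1.24), Neo1 (1.24), C5ar1 (1.03, SE 0.11), Xlr4a (1.00), Tarm1 (0.97), the interferon-induced chemokine Cxcl10 (0.90) and the lysosomal channel gene Mcoln3 (0.89). The 10 decreases that met the rule were Ifi44 (-0.99, SE 0.16), Ly86 (-0.98, SE 0.16), Ifi44l (-0.95), the ribosomal protein gene Rpl29 (-0.71, SE 0.09), its near neighbour Abhd14b (-0.66), the urokinase gene Plau (-0.62), Cxcl14 (-0.45), Olfml3 (-0.42), Pdlim5 (-0.32) and Cd74 (-0.32). The count was 35 without the library labelled Cbl-b-/- 2, 41 without Cbl-b-/- 3 and 37 without WT 1, and DESeq2 called 145.

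Of the 25 inflammatory cytokine and NF-kB target genes, 5 rose, 0 fell and 20 did not pass in the libraries labelled Cbl-b-/-, with 9 and 0 adjusted over the list alone (adjusted p = 4.6e-13, and adjusted p = 0.036 with an estimated correlation). Beside Cxcl2 they were Cxcl1 (1.37, SE 0.24), Socs3 (0.84), Icam1 (0.44) and Tnf (0.42, the last of the 5 risers and chosen after its values were seen). The remaining calls were lost with an estimated correlation. The monocyte list had 1 riser of 10, the matrix proteoglycan gene Vcan (0.71), and 9 not passing (5 rose adjusted over the list alone; adjusted p = 7.1e-04, adjusted p = 0.29 with an estimated correlation). Among the 17 chemokine receptor and migration genes C5ar1 alone rose and 16 did not pass (5 rose adjusted over the list alone; adjusted p = 7.2e-04, adjusted p = 0.090 with an estimated correlation). The ERK and immediate early list had 2 risers of 24, Ier3 (0.58) and Ier2 (0.48), and 22 not passing (3 rose adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.37 with an estimated correlation). In the MHC class II list Cd74 fell and 12 of 13 did not pass (4 fell adjusted over the list alone; adjusted p = 0.0033, adjusted p = 0.36 with an estimated correlation). Of 8 stromal and endothelial genes, the collagen gene Col1a1 fell (-2.30, SE 0.41), from 1.68 ± 0.84 to 0.312 ± 0.16 CPM, and 7 did not pass (2 fell adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.36 with an estimated correlation). The mitosis list had no member past the threshold, nor when adjusted over the list alone, and a median of 0.06 (adjusted p = 6.5e-04, adjusted p = 0.36 with an estimated correlation); its smallest p values belonged to Aurka (0.18, SE 0.05, adjusted p = 0.28) and Ccnb2 (0.18, SE 0.06, adjusted p = 0.34). The macrophage identity list likewise had 0 of 24 past the threshold by either adjustment and a median of -0.07 (adjusted p = 0.041, adjusted p = 0.37 with an estimated correlation), with Apoe at -0.22 (adjusted p = 0.36) and Lpl at -0.63 (adjusted p = 0.55).

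**Figure D2:**
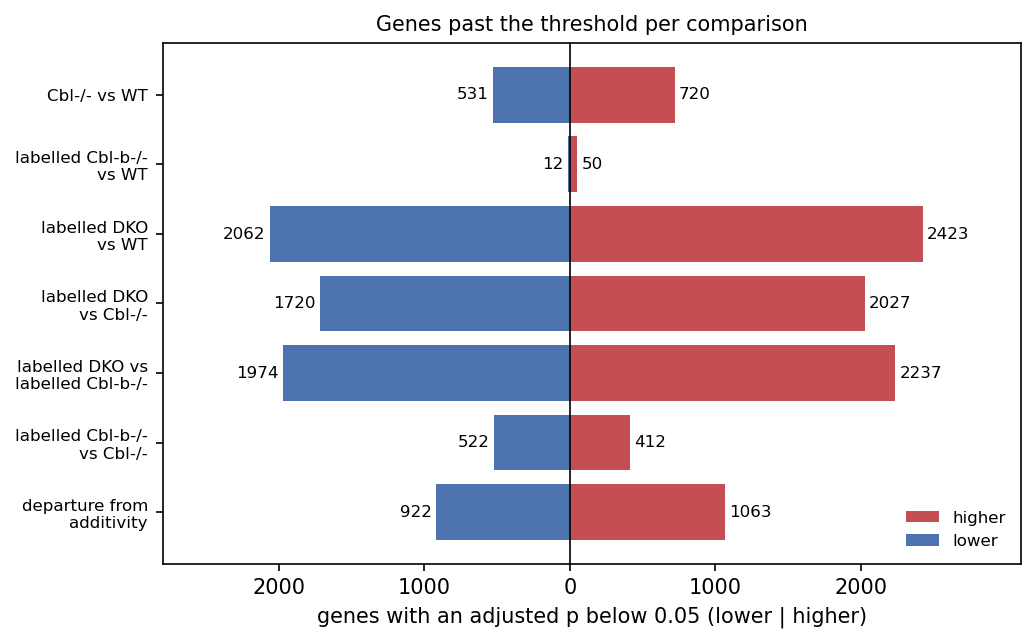
Numbers of genes (horizontal axis) with an adjusted p below 0.05 in each of the 6 pairwise comparisons and for departure from additivity; red bars are higher and blue bars lower in the group named first. The libraries labelled DKO against WT had 2423 higher and 2062 lower, and those labelled Cbl-b-/- against WT had 50 and 12.

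The libraries labelled DKO differed from WT in 4485 genes. All 26 interferon response genes and 22 of 25 inflammatory genes rose, as did 8 of 10 monocyte and 7 of 9 granulocyte genes, and 14 of 24 macrophage identity genes fell. With an estimated correlation the inflammatory and granulocyte lists passed (adjusted p = 0.023 and 0.027), and the interferon, monocyte and macrophage lists did not (adjusted p = 0.088 for each). Apoe, the lipid carrier, fell from 339 ± 31 to 54.4 ± 5.0 CPM (SD, n = 3). S100a9 and S100a8, the subunits of calprotectin, rose from 0.717 ± 0.089 to 31.0 ± 7.2 CPM and from 1.16 ± 0.10 to 16.4 ± 6.0. Acod1 reached 103 ± 5.3 CPM against 5.23 ± 0.38 in WT.

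There were 2423 genes higher and 2062 lower, 4485 in all, with 520 higher and 279 lower by at least 2-fold. Scaling by total counts turned the split to 1773 higher and 2873 lower. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) had a log2 fold change of 5.43 (SE 0.22, adjusted p = 1.9e-11) and Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573) 4.30 (SE 0.15). Further increases within the naming rule were S100a8 (3.84), the protease inhibitor gene Serpinb1a (3.80), the monocyte chemokine Ccl7 (3.67, SE 0.17), Flrt3 (3.49), Cyp2s1 (3.19), the activation antigen gene Cd69 (3.05), complement C3 (2.85, SE 0.14) and Pianp (2.82). The largest decrease within the rule was that of Rpl29 (ENSMUSG00000048758, chromosome 9, 106429454 to 106431568), from 332 ± 12 to 5.66 ± 1.3 CPM (-5.87, SE 0.12, adjusted p = 7.2e-15). Ribosomal protein genes have many processed copies in the genome, so Rpl29 is uncertain. It was followed by the organic anion transporter gene Slco2b1 (-4.82), Fcrls (-3.89), Apoe (-2.64, SE 0.08), Dmpk (-2.59), the integrin gene Itga8 (-2.46), the prostaglandin-degrading enzyme gene Hpgd (-2.43), Cxcl14 (-2.43), the cholesterol 25-hydroxylase gene Ch25h (-2.41) and Tox2 (-2.32).

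All 26 interferon response genes rose in the libraries labelled DKO, also when adjusted over the list alone, with a median of 1.82 (adjusted p = 4.5e-24, adjusted p = 0.088 with an estimated correlation). Gbp2, which encodes a guanylate-binding protein, rose by 2.17 (SE 0.13), from 6.40 ± 0.65 to 28.7 ± 3.7 CPM, and Gbp3 by 1.88 (SE 0.14). Of 25 inflammatory cytokine and NF-kB target genes, 22 rose, 0 fell and 3 did not pass, with the same counts adjusted over the list alone (adjusted p = 1.1e-15, and adjusted p = 0.023 with an estimated correlation). Ccl2 rose from 137 ± 14 to 579 ± 31 CPM, Il1rn, an antagonist of interleukin 1, by 2.03 and Socs3 by 1.92. Of the 13 genes of MHC class II presentation 9 rose, 1 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.0082, adjusted p = 0.20 with an estimated correlation). Cd80, on this list but not itself an MHC class II gene, was at 1.19 and Cd74 at 0.44.

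Of 24 macrophage identity genes, 14 fell, 4 rose and 6 did not pass in the libraries labelled DKO (15 and 5 adjusted over the list alone; adjusted p = 4.0e-05, adjusted p = 0.088 with an estimated correlation). Apoe, the fractalkine receptor Cx3cr1 (-1.04), complement C1qb (-1.11) and the Fc receptor Fcgr3 (-0.97) fell, while Fcgr1 (0.82), Cd14 (0.66), Cd36 (0.86) and Lpl (1.41) rose. Csf1r fell by 0.37 (SE 0.06), whereas the abundant macrophage genes Lyz2 (-0.15, adjusted p = 0.14) and Cd68 (-0.14, adjusted p = 0.11) did not pass. In this comparison Fcgr1, Cd14, Cd36, Lpl, Csf1r, Lyz2 and Cd68 lie outside the naming rule and were chosen after their values were seen. Of 9 neutrophil and granulocyte genes 7 rose, 1 fell and 1 did not pass (7 and 2 adjusted over the list alone; adjusted p = 1.0e-04, and adjusted p = 0.027 with an estimated correlation). The granule protein genes Ngp and Ltf rose from 0.572 ± 0.21 to 14.8 ± 1.2 CPM and from 0.771 ± 0.29 to 9.83 ± 0.83. Of 10 monocyte genes 8 rose, 0 fell and 2 did not pass, also adjusted over the list alone (adjusted p = 4.4e-05, adjusted p = 0.088 with an estimated correlation). Vcan rose from 12.8 ± 0.71 to 75.4 ± 10 CPM and Ly6c2, a marker of classical monocytes, from 0.107 ± 0.095 to 6.04 ± 0.69. Of 8 stromal and endothelial genes 6 rose, 0 fell and 2 did not pass, also adjusted over the list alone (adjusted p = 0.0036, adjusted p = 0.15 with an estimated correlation), with Bgn reaching 3.31 ± 0.49 CPM and Col1a1 6.81 ± 1.0. The haematopoietic progenitor list had 5 risers, among them Hoxa9 (3.06) and the stem cell factor receptor gene Kit (2.07), 1 that fell and 1 not passing of 7, also adjusted over the list alone (adjusted p = 0.046, adjusted p = 0.15 with an estimated correlation). Mitochondrial genes took 2.58 ± 0.55% of counts against 3.30 ± 0.24% in WT (SD, n = 3), with 2.35%, 2.18% and 3.21% in the 3 libraries labelled DKO. The last of these, DKO 3, also stood apart from DKO 1 and DKO 2 in the chi-square per degree of freedom of their counts (44.7 and 55.3, against 10.2 between those 2).

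Metabolic and matrix genes moved as well. The cholesterol synthesis list had 12 of 22 higher, 1 lower and 9 not passing (13 and 2 adjusted over the list alone; adjusted p = 5.5e-04, and adjusted p = 0.027 with an estimated correlation), with the pathway enzyme gene Sqle at 0.38. Of 22 glycolysis and hypoxia genes 12 rose, 0 fell and 10 did not pass (15 and 0 adjusted over the list alone; adjusted p = 1.5e-04, adjusted p = 0.15 with an estimated correlation), with Ldha at 0.41 and Pgk1 at 0.39. Among 18 LXR target and lipid efflux genes 10 rose, 3 fell and 5 did not pass (11 and 3 adjusted over the list alone; adjusted p = 0.0019, adjusted p = 0.17 with an estimated correlation); the sterol exporter Abcg1 rose by 1.25 and the desaturase gene Scd2 by 1.26, against the fall of Apoe. Of 24 lysosomal genes 11 rose, 3 fell and 10 did not pass (13 and 3 adjusted over the list alone; adjusted p = 0.0038, adjusted p = 0.24 with an estimated correlation). The bone-degrading protease gene Ctsk rose by 1.80, and in the osteoclast list, which also holds Ctsk, 5 of 9 rose, 2 fell and 2 did not pass by either adjustment (adjusted p = 0.045, adjusted p = 0.24 with an estimated correlation). Of 15 matrix protease and matrix genes 10 rose, 3 fell and 2 did not pass by either adjustment (adjusted p = 0.0099, adjusted p = 0.094 with an estimated correlation), with the membrane protease Mmp14 at 2.73 and osteopontin, Spp1, at 1.18. In the oxidative stress list 6 of 14 fell, 1 rose and 7 did not pass by either adjustment (adjusted p = 0.015, adjusted p = 0.20 with an estimated correlation), with the glutathione synthesis genes Gclc at -0.72 and Gclm at -0.66. The ERK and immediate early list did not pass (adjusted p = 0.92), with 10 genes up, 7 down and 7 not passing (11 and 8 adjusted over the list alone), a median of 0.12 and a mean of -0.13. Its members Dusp6 (-1.36) and Etv5 (-1.03) fell and Egr2 (1.41) rose.

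**Figure D3:**
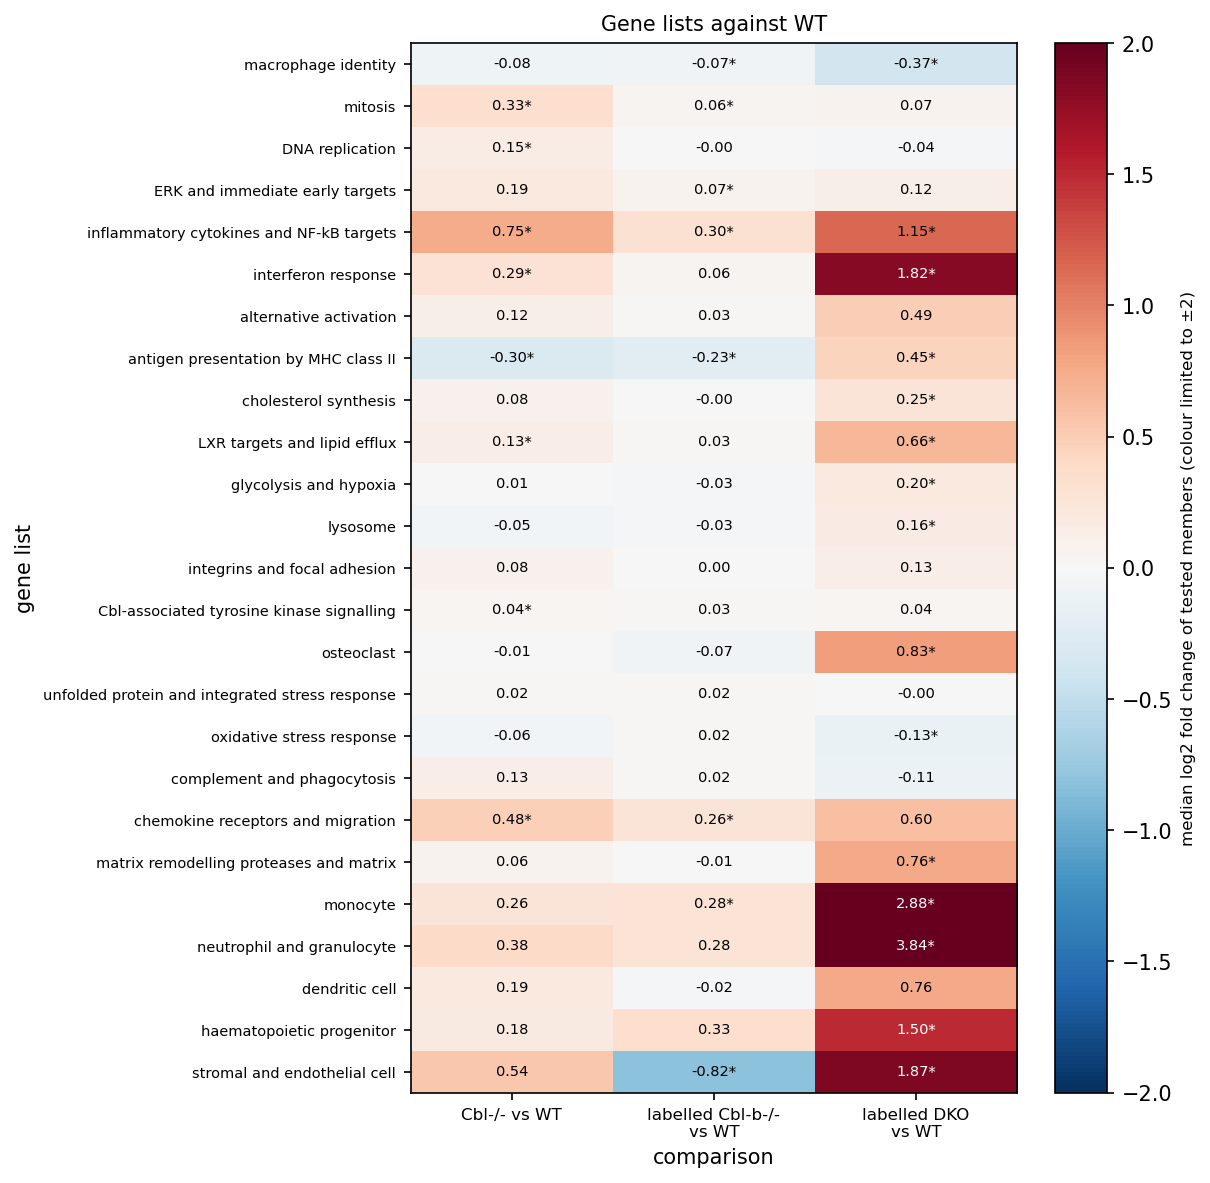
Median log2 fold change against WT (colour and printed value; colour limited to 2 in either direction) of the tested members of 25 gene lists (rows) in the 3 comparisons with WT (columns); an asterisk marks an adjusted camera p below 0.05 with the preset correlation. The libraries labelled DKO have 1.82 for interferon response, 3.84 for neutrophil and granulocyte and -0.37 for macrophage identity.

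**Figure D4:**
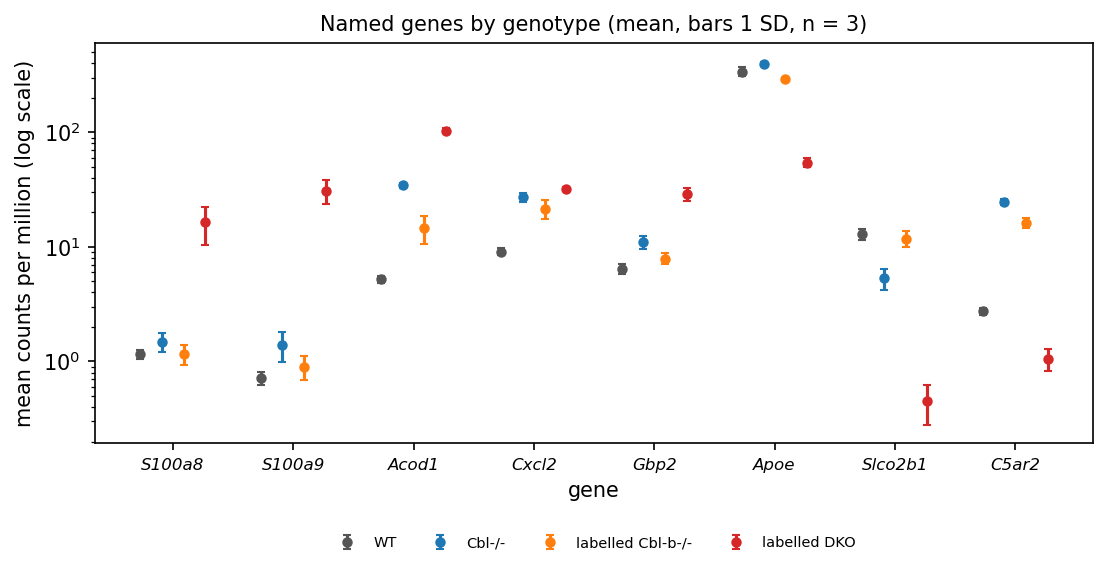
Mean CPM (vertical axis, log scale) of 8 named genes in the 4 genotypes; bars are 1 SD of 3 libraries. C5ar2 is higher than in WT (2.74) in Cbl-/- (24.7) and in the libraries labelled Cbl-b-/- (16.3), and lower (1.06) in those labelled DKO.

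The libraries labelled DKO were also set against Cbl-/- and against those labelled Cbl-b-/-. Against Cbl-/-, Ifi44l was higher by 8.74, Hmga1b by 7.12, Stard13 by 5.05, Ifi44 by 5.03 and S100a9 by 4.50, and the largest decreases within the naming rule were Rpl29 (-5.90), C5ar2 (-4.52), Slco2b1 (-3.56), Fam162a (-3.51) and Fcrls (-3.18). Cbl was lower by a further step (-0.45, SE 0.06, adjusted p = 5.1e-05). There were 2027 genes higher and 1720 lower, or 1362 and 2747 with scaling by total counts. The mitosis list was lower than in Cbl-/-, with 14 of 22 down, 0 up and 8 not passing (15 and 0 adjusted over the list alone; adjusted p = 4.5e-07, adjusted p = 0.098 with an estimated correlation). Of 24 DNA replication genes 13 were lower, 2 higher and 9 did not pass (15 and 2 adjusted over the list alone; adjusted p = 3.0e-05, and adjusted p = 0.041 with an estimated correlation). Of 9 granulocyte genes 7 were higher, 1 lower and 1 did not pass by either adjustment (adjusted p = 1.7e-05, and adjusted p = 0.033 with an estimated correlation). Against the libraries labelled Cbl-b-/-, S100a9 (5.14), Serpinb1a (3.87), S100a8 (3.80), Ccl7 (3.30) and Met (3.17) rose the most of the genes that met the naming rule, and Rpl29 (-5.16), Slco2b1 (-4.70), Fcrls (-3.95), C5ar2 (-3.92) and Itga8 (-2.46) fell the most. The counts were 2237 higher and 1974 lower, or 1543 and 3207 by total counts. With only the compared genotypes in the fit the total was 2760, against 4211. Of 25 inflammatory genes 17 were higher, 0 lower and 8 did not pass by either adjustment (adjusted p = 4.5e-10), of 22 cholesterol synthesis genes 13 were higher, 2 lower and 7 did not pass (16 and 2 adjusted over the list alone; adjusted p = 4.2e-04), and of 9 granulocyte genes 7 were higher and 2 lower by either adjustment (adjusted p = 3.6e-04). Each of these 3 lists had an adjusted p = 0.031 with an estimated correlation. The interferon response list had 26 of 26 up in both comparisons and by either adjustment (adjusted p = 5.3e-24 and 3.1e-24, adjusted p = 0.083 and 0.10 with an estimated correlation). The libraries labelled Cbl-b-/- had 412 genes higher and 522 lower than Cbl-/-. Hmga1b (6.57), Ifi44l (6.31), Stard13 (5.56), Cers4 (3.90) and Atp10d (2.61) were higher, and Uchl1 (-4.03), Nectin1 (-3.05), Fkbp9 (-2.75), Igf2bp3 (-2.61) and Fam162a (-2.52) lower. The mitosis list was lower, with 15 of 22 down and 7 not passing (21 adjusted over the list alone; adjusted p = 9.1e-16, adjusted p = 0.052 with an estimated correlation). This count of 934 genes was 533, 550 and 558 without Cbl-/- 1, 2 and 3, and 1712 with only the compared genotypes in the fit.

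The 4 genotypes allow a test of whether the libraries labelled DKO departed from the sum of the effects in Cbl-/- and in the libraries labelled Cbl-b-/-. They did so for 1985 genes, 1063 above the sum and 922 below it, or 711 and 1719 with scaling by total counts. The contrast assumes that Cbl-/- and the libraries labelled DKO share the same Cbl change and background, which the counts cannot show. Cbl had 49.3 to 54.0 CPM in Cbl-/- and 35.0 to 41.0 in the libraries labelled DKO. Gt(ROSA)26Sor, chosen after its values were seen, had 5.49 to 6.77 and 2.29 to 3.32. Departures therefore cannot be ascribed to an interaction of both losses alone. C5ar2 and C5ar1, higher than WT in Cbl-/- and in the libraries labelled Cbl-b-/-, were lower than WT in the libraries labelled DKO (1.06 ± 0.23 and 104 ± 8.7 CPM, SD, n = 3), with departures of -7.09 (SE 0.19) and -3.95 (SE 0.16). Ifi44l and Ifi44, lower than WT in both of these groups, reached 29.9 ± 2.1 and 119 ± 22 CPM, with departures of 9.69 (SE 0.35) and 6.01 (SE 0.25). Other genes far above the sum were Hmga1b (7.38), Stard13 (5.24) and Plbd1 (4.44), and far below it Rpl29 (-5.18), Slco2b1 (-3.43) and Fam162a (-3.39). The departures of Hmga1b and Stard13 rest on their low levels in Cbl-/- (2.11 and 0.361 CPM). They had 242 and 20.2 CPM in WT, and 297 and 12.6 in the libraries labelled DKO. Large parts of the departures of Ifi44l, Ifi44 and Plbd1 also come from Cbl-/-, with log2 fold changes against WT of -7.26, -3.39 and -2.62. Ifi44l had only 6 counts over the Cbl-/- libraries (0.0768 CPM), and Plbd1 had 52 (0.582 CPM). Summed with its copy Hmga1, Hmga1b had log2 ratios to WT of 0.019 in Cbl-/-, -0.23 in the libraries labelled Cbl-b-/- and 0.34 in those labelled DKO. In the interferon response list 25 of 26 genes lay above the sum, 0 below and 1 did not pass by either adjustment (adjusted p = 3.9e-21, adjusted p = 0.10 with an estimated correlation). The MHC class II list had 6 of 13 above and 7 not passing (7 above adjusted over the list alone; adjusted p = 2.9e-06, adjusted p = 0.096 with an estimated correlation), with Cd74 at 1.38 and H2-Eb1 at 1.89, both chosen after their values were seen. No list's call for this contrast held with an estimated correlation.

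The comparisons with WT shared genes. Cbl-/- and the libraries labelled Cbl-b-/- had 52 genes changed in the same direction, 45 higher and 7 lower, and 1 in opposite directions, where independent lists of these sizes would share 3.34. Acod1, Cxcl2, C5ar2, Neo1 and Pira2 were higher and Ifi44 lower in both. Cbl-/- and the libraries labelled DKO shared 746 in the same direction, against 224 for independent lists, with 91 opposite, and the libraries labelled Cbl-b-/- and labelled DKO shared 50 against 11.5, with 7 opposite. Across genes, which are not independent replicates, the fold changes correlated with r = 0.25, 0.38 and 0.17 in these 3 pairs of comparisons, below the 0.47, 0.49 and 0.48 of unchanged groups simulated with a shared simulated WT. Their covariances were 0.0383, 0.106 and 0.0350, against 0.0263, 0.0262 and 0.0260 simulated. Unchanged groups differ from WT by spread alone, part of it from the shared WT, so a lower r does not mean weaker sharing. In these simulations, which held no changed genes, at most 0, 1 and 1 genes were called in the same direction in both comparisons of a pair. The 3 WT libraries cannot be split in parts of 2, so part of the excess may come from the shared WT libraries. Without WT 1 the overlaps were 28, 417 and 29, and without WT 2 that of Cbl-/- and the libraries labelled DKO was 453. With DESeq2 the 3 overlaps were 97, 910 and 106.

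The Y-linked genes of the sex check were expressed in every library. In Cbl-/- they were lower than in WT, Ddx3y by -0.53 (SE 0.10, adjusted p = 0.0025), Kdm5d by -0.75 (SE 0.07, adjusted p = 2.6e-06), Uty by -0.77 (SE 0.11, adjusted p = 2.4e-04) and Eif2s3y by -0.78 (SE 0.11, adjusted p = 2.0e-04). Ddx3y had 60.2 ± 3.3 CPM in Cbl-/- against 86.9 ± 1.9 in WT (SD, n = 3). In the libraries labelled DKO Kdm5d was at -0.30 (adjusted p = 0.0038) and Eif2s3y at 0.38 (adjusted p = 0.011), while Ddx3y (-0.09, adjusted p = 0.51, but -0.249 and adjusted p = 0.0050 without DKO 3) and Uty (0.01, adjusted p = 0.95) did not pass, and none of the 4 passed in those labelled Cbl-b-/-. Uty in the libraries labelled DKO changed sign with scaling by total counts.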

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

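All tests of this part apart from the 2 on gene position, the list tests and the additivity test were chosen only after the result was seen. The results here stood out because the effect in the libraries labelled DKO differed from the sum of those in Cbl-/- and in the libraries labelled Cbl-b-/- in a test of that difference.

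The libraries labelled DKO departed from additivity for 1985 genes. The contrast cannot separate an interaction of both losses from other differences between Cbl-/- and the libraries labelled DKO. In 60 arrangements of the 12 libraries into 4 groups of 3, 2 gave as many by edgeR, the real one included, and the highest other arrangement called 2275 genes, more than the real one. Other arrangements mix genotypes within groups, so their counts do not test additivity. The highest one kept the 3 libraries labelled DKO together, in the place of WT, and the 3 WT libraries together, in the place of Cbl-b-/-, so its contrast holds the difference between these 2 genotypes.

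The single genes far above the sum were Ifi44l (9.69), Hmga1b (7.38), Ifi44 (6.01), Stard13 (5.24) and Plbd1 (4.44). Those far below it were C5ar2 (-7.09), Rpl29 (-5.18), C5ar1 (-3.95), Slco2b1 (-3.43) and Fam162a (-3.39). The values of Hmga1b and Stard13 rest on their low levels in Cbl-/- (2.11 and 0.361 CPM). Those of Ifi44l, Ifi44 and Plbd1 rest in large part on theirs (0.0768, 3.58 and 0.582 CPM). The sum of Hmga1 and Hmga1b showed no departure near 7.38, with log2 ratios to WT between -0.23 and 0.34 in the 3 other groups. A smaller departure of the sum was not tested. Median departures of the lists past the threshold were 3.02 for neutrophil and granulocyte, 2.11 for stromal and endothelial cell, 1.10 for monocyte, 1.09 for interferon response, 0.90 for osteoclast, 0.70 for matrix remodelling proteases, 0.44 for MHC class II, 0.32 for lysosome, 0.22 for LXR targets, 0.21 for glycolysis and hypoxia and 0.15 for cholesterol synthesis. They were -0.40 for complement and phagocytosis, -0.30 for mitosis, -0.24 for oxidative stress, -0.23 for macrophage identity, -0.23 for DNA replication and -0.16 for the ERK and immediate early list. None of these list calls held with an estimated correlation.

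Some changes of at least 2-fold in Cbl-/- may not follow from the loss of Cbl, and strain-derived DNA linked to that gene is a candidate explanation for part of them, since the odds of such a change were 3.87 times higher within 10 Mb of Cbl than elsewhere (Fisher's exact test, 7 of 119 genes against 199 of 12521, adjusted p over 6 tests = 0.020). It stays open, because the odds ratio near Cblb, which is not targeted in Cbl-/-, was 3.72 (3 of 52, adjusted p = 0.16). In the libraries labelled DKO the odds ratio near Cbl was 1.37 (10 of 119, adjusted p = 0.68). That value cannot decide, since 6.29% of genes elsewhere changed there, against 1.59% in Cbl-/-. Near Cbl the shares were 8.40% in the libraries labelled DKO and 5.88% in Cbl-/-. Segments elsewhere in the genome stay open too. Of 196 such genes outside these windows, 38.8% had another within 1 Mb. In 1000 random sets the median was 28.1%, the upper 95% bound 36.2% and the highest value 40.3%. Families of co-regulated genes would cluster as well. In the libraries labelled Cbl-b-/-, 61.5% of 13 genes had such a neighbour too (highest random value 30.8%). In those labelled DKO 66.5% of 784 genes did, below the bound of 68.5%. That value decides little, since random sets of that size already had a median of 64.8%. For Hmga1b the sum of Hmga1 and Hmga1b counts hardly moved (log2 ratio 0.019, 404 ± 51 to 409 ± 3.2 CPM, SD, n = 3), which is consistent with reads being assigned to the other copy, by a strain variant or by counting. These tests leave most of the 207 changes unexplained, and the loss of Cbl itself remains open for them as the biological explanation that the design names. Cbl was lower in the libraries labelled DKO too (-1.90), yet Uchl1 had 24.6 CPM there, against 201 in Cbl-/- and 14.1 in WT. Cers4 had 31.2 CPM, against 2.55 and 38.9, whereas Acod1 had 103, against 34.4 and 5.23. Of the 1251 genes changed in Cbl-/-, 746 changed in the same direction in the libraries labelled DKO and 91 in the opposite one.

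Monocyte and granulocyte genes rose and macrophage genes fell in the libraries labelled DKO. A lower share of macrophages as the whole cause would lower the genes that macrophages alone express. Of the macrophage identity list 4 genes rose (Cd14, Fcgr1, Cd36 and Lpl), but cells in the place of macrophages could express these too. Of the 24 genes on that list 13 are also on other lists, so the 4 risers cannot decide. Granulocytes or their precursors among the adherent cells could add such transcripts, and 7 of 9 granulocyte genes rose, but Mmp8 fell from 31.4 ± 3.0 to 20.3 ± 3.2 CPM (SD, n = 3) and Csf3r was at -0.32 (adjusted p = 0.10), both chosen after their values were seen, so a small number of such cells and a change within the macrophages cannot be told apart. Levels stayed low, with S100a9 at 31.0, S100a8 at 16.4 and Ngp at 14.8 CPM against 14078 CPM for Lyz2. Only adherent cells were taken, but how many granulocytes or precursors remained among them was not measured. Neither point sets a limit on their share. Of the 16 granulocyte list genes 10 were in the table, 4 of them above 1 CPM in WT and 1 also on another list; the monocyte list had 11, 5 and 3.

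Each of the 6 comparisons between genotypes allows 10 splits of its 6 libraries, too few for a share below 0.05. In each, 1 of the 10 splits, the real one, called as many genes as the real one, with real values of 1251, 62, 4485, 3747, 4211 and 934 and 0 for the highest other split by edgeR.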

How the results depend on the processing

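Cbl-b-/- and DKO here stand for the libraries so labelled. All alternatives here were planned, and none was chosen only after the result was seen. The values below cover the main results, namely the numbers of genes, lists and overlaps and Cbl and Cblb against WT, and genes that changed direction. Given are those that changed direction or side of the threshold, or moved by more than 1.5 times, and ranges. The cause was not tested unless stated. For other named genes and single lists, 114 results lost a call and 14 gained a call, leave-one-out fits not counted. These are not listed. With only the compared genotypes in the fit, 2753 genes were called for Cbl-/- against WT, 1712 for Cbl-b-/- against Cbl-/- and 2760 for DKO against Cbl-b-/-, each fit having its own estimate of the spread. DESeq2 called 145 genes for Cbl-b-/- against WT, and its overlaps of that comparison with Cbl-/- and with DKO were 97 and 106. With an estimated correlation the lists called were 3 for Cbl-/-, 1 for Cbl-b-/- and 3 for DKO against WT, 2 and 3 for DKO against Cbl-/- and Cbl-b-/-, 0 for Cbl-b-/- against Cbl-/- and 0 for departure from additivity. Under the other alternatives the lists called numbered 8 to 12, 6 to 9, 12 to 19, 15 to 17, 13 to 17, 6 to 9 and 12 to 17 in this order, against 8, 8, 15, 17, 15, 8 and 17 in the fit reported, so single list calls were lost or gained. Cblb in Cbl-/- lost its call without the filter at a log2 fold change of 0.205. With scaling by total counts Cbl in Cbl-b-/- moved from -0.01 to 0.012, Cblb between DKO and Cbl-/- to -0.021 and Uty in DKO to -0.061, none of them called. Scaling by total counts also lowered the percent of called genes that were higher from 54.0 to 38.2 for DKO against WT, from 54.1 to 33.1 for DKO against Cbl-/-, from 53.1 to 32.5 for DKO against Cbl-b-/- and from 53.6 to 29.3 for departure from additivity. Leaving out 1 library at a time gave 733 to 978 genes for Cbl-/- against WT, 35 to 75 for Cbl-b-/- against WT, 533 to 737 for Cbl-b-/- against Cbl-/- and 3355 to 4797 for DKO against WT. Overlaps ranged from 28 to 39, 417 to 634 and 29 to 38 for Cbl-/- with Cbl-b-/-, Cbl-/- with DKO and Cbl-b-/- with DKO. Cbl in Cbl-b-/- ranged from -0.030 to 0.0067, Cblb in Cbl-/- from 0.157 to 0.239 with its call lost in all 6 fits, Ddx3y in DKO from -0.249 (without DKO 3, where it passed) to 0.036, Eif2s3y in Cbl-b-/- from -0.023 to 0.087, with -0.017 without Cbl-b-/- 1, and Uty in DKO from -0.148 to 0.093, with -0.0083 without WT 2. With the replicate number as a block the counts were 1139, 60 and 4280 for Cbl-/-, Cbl-b-/- and DKO against WT, and Cblb in Cbl-/- lost its call at 0.205. The numbers did not pair the libraries: the 18 pairs with a shared number correlated at -0.054 to 0.052, and 3 of 12 libraries correlated best with their own number. Depth limits genes of a few CPM or less, such as Col1a1 and Ly6c2.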

Other observations

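The tests of Y-linked genes below were chosen only after the result was seen, as were Gt(ROSA)26Sor and, in the libraries labelled DKO, Abhd14b. In the libraries labelled DKO the complement and phagocytosis list did not pass (adjusted p = 0.072), with 9 of 20 genes down, 4 up and 7 not passing (9 and 5 adjusted over the list alone). C3 rose by 2.85 while Gas6, a ligand of the receptor Mertk, fell by 1.72. The list of integrins and focal adhesion did not pass either (adjusted p = 0.61), yet 9 of 23 rose and 7 fell (11 and 7 adjusted over the list alone), among them Src at 2.29, Itgb5 at -1.21 and Itga6 at -0.78. In the alternative activation list 7 of 12 rose, 3 fell and 2 did not pass (8 and 3 adjusted over the list alone; adjusted p = 0.11), with the chitinase-like gene Chil3 at 5.75 and the scavenger receptor Cd163 at -2.27. In Cbl-/- that list did not pass (adjusted p = 0.21), with 2 of 12 up, 1 down and 9 not passing, also adjusted over the list alone; Cd163 fell (-0.83) and the mannose receptor gene Mrc1 rose (0.62).

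Gt(ROSA)26Sor, a noncoding transcript at a locus widely used for inserting transgenes, had 10, 9 and 3 counts in the WT libraries, 208, 141 and 196 in Cbl-/-, 10, 19 and 2 in those labelled Cbl-b-/- and 83, 72 and 137 in those labelled DKO. Rpl29 and its neighbour Abhd14b on chromosome 9 were both lower in the libraries labelled Cbl-b-/- (203 ± 18 and 8.46 ± 0.59 CPM) and labelled DKO (5.66 ± 1.3 and 4.67 ± 0.30) than in WT (332 ± 12 and 13.3 ± 0.75).

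The 4 Y-linked genes were lower in Cbl-/- under each scaling, with a median of -0.74 by total counts, where the median of all genes was 0.012. The scalings hardly moved the median of all genes and so tested little, but 1 factor per library moves all genes alike, and the distance between these 2 medians argues against the scaling of the libraries as the cause. Female cells in these cultures could lower them, but only 1 of 4 X-linked partners rose (Eif2s3x, 0.46, adjusted p = 2.3e-05, which also rose in the libraries labelled DKO, by 0.28, where Eif2s3y rose), with Kdm6a at 0.22 (adjusted p = 0.074), Kdm5c at 0.19 (adjusted p = 0.11) and Ddx3x at -0.04 (adjusted p = 0.76), which decides neither way. Xist is absent from the table, so a mixture of sexes, loss of the Y chromosome in some cells and lower expression cannot be told apart.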
